A study of Marmota monax with 4 samples.

How the data were processed

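RNA was measured in 4 populations of live cells sorted by flow cytometry from the liver of 1 woodchuck (Marmota monax) that carried woodchuck hepatitis virus and a liver tumour, with the tissue taken away from visible tumour. The sort separated cells by surface CD14, a lipopolysaccharide co-receptor found on monocytes and macrophages, and by nanoparticle (NP) signal. Each of the 4 combinations gave 1 population and 1 library, written here as CD14+ or CD14- followed by NP+ or NP-. Groups were taken from the cell population label of each sample, and each column of the count table matched the label of exactly 1 sample.

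Per the labels' protocols, cDNA was made by random priming with template switching, ribosomal cDNA was cleaved with probes, and paired-end reads were sequenced on an Illumina instrument. The deposited values are whole-number read counts per gene identifier, with no normalization by the authors visible in them, since the 4 columns have different totals. Per the submitters' processing notes, the tools named are bcl2fastq, STAR 2.6, featureCounts, Subread and edgeR. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. All identifiers start with ENSMMMG, and none of the sources used here says which species' annotation that is. It is therefore open whether the reads were counted against woodchuck gene models or those of a related species. In the second case reads would be lost where the sequences diverge, and each feature would follow the other species' gene model. Comparisons of 1 feature between libraries share that loss, while levels of different features do not. Overlapping, antisense and near-identical genes may therefore have shared or lost reads. No molecular identifiers are mentioned, so PCR copies count as separate reads.

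The deposited table holds 24024 gene identifiers, called features below. The files do not pair these identifiers with gene symbols, and the woodchuck RefSeq gene table used here lists no identifiers of this kind, so no match was possible. Identifiers were therefore used exactly as deposited, at most 2 per direction are printed, and no coordinates are given. The 29 lists of cell type markers and pathways that had been fixed before the data were examined could not be applied. The CD14 transcript was not analysed here for the same reason, so the counts give no check of the sort labels.

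Counts were scaled to CPM (counts divided by the library total in units of 1e+06) with TMM factors from edgeR 4.0.16 in R 4.3.3, computed over all 4 libraries. A log2 ratio is the difference of log2(CPM + 1) between 2 libraries, a scale that understates the change of low features. A feature was called higher or lower when this ratio was at least 2-fold and the higher library had at least 10 CPM, which corresponds to between 176 and 194 counts. With 1 library per group there is no replicate spread, so no test was run and no p-value is given, and an observed difference has no replicate check. An additive model over the 4 libraries was not used as a test, because its residual would be the interaction between the 2 sorts and not replicate error. Ratios of printed features have exact (Clopper-Pearson, conditional binomial) 95% intervals, which cover counting error only. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

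The call was tested on simulated data for each of the 4 comparisons over all 24024 features, with Poisson counting noise and 200 features seeded at 3-fold or 6-fold, drawn from those with a mean of at least 10 CPM in the 2 libraries. It recovered 100% of the features seeded at 3-fold and 100% of those seeded at 6-fold in each comparison and called 0 unchanged features. This checks the calculation on well-expressed features and says nothing of low ones. These simulations contain no biological or preparation variance.

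The rule for naming genes, fixed before the data were examined, ranked features at least 4-fold higher in both NP+ libraries than in the NP- library of the same CD14 sort, with at least 20 CPM in each of the libraries where the feature was higher, by the smaller of the 2 ratios, and likewise for lower features. The first 2 per direction are printed. The parts of that rule that needed gene symbols were not applied. Alternatives to the scaling (plain CPM, and the median-of-ratios size factors of DESeq2 1.42.0), the minimum level and the pseudocount were also fixed before the data were examined. Thinning all libraries to the smallest total was added afterwards.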

Results

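The 4 sorted liver cell populations from 1 virus-positive, tumour-bearing woodchuck were profiled by RNA sequencing. Cells with nanoparticle signal were compared with cells without it, within and outside the CD14+ compartment. Woodchucks infected with woodchuck hepatitis virus develop liver cancer spontaneously and serve as a model of virus-associated liver cancer. The CD14+NP- library held 20743633 counts, the CD14-NP- library 17433846, the CD14-NP+ library 17477941 and the CD14+NP+ library 20057980. Of the 24024 features, 5315 had no read in any library and 14779 had a read in all 4. The CD14-NP- library had a read for the most features, 17403, against 16626 in CD14+NP-, 16177 in CD14-NP+ and 16568 in CD14+NP+. At equal depth the numbers were 17403, 16581, 16176 and 16493 in the same order. The most abundant feature took 4.997% of counts in CD14-NP-, 4.65% in CD14-NP+, 3.71% in CD14+NP+ and 3.31% in CD14+NP-, and the 100 most abundant took between 24.5% and 27.3%. Across the 10619 features with at least 10 CPM in any library, the 2 NP+ libraries were the most alike of the 6 pairs (Pearson r = 0.92, Spearman rho = 0.93, across features, which are not independent replicates). The least alike were CD14-NP- and CD14+NP+ (r = 0.71, rho = 0.74), and the other 4 pairs had r between 0.80 and 0.87.

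The first comparison asked which transcripts differed with nanoparticle signal among CD14+ cells. Of 9533 features compared, 875 were at least 2-fold higher and 1073 at least 2-fold lower in the CD14+NP+ library than in the CD14+NP- library, or 20.4% in all. The 2-fold balance depended on the scaling, with 928 higher and 995 lower under plain CPM and 787 and 1144 under DESeq2 size factors. The larger differences lay mostly on the lower side: 464 features were at least 4-fold lower and 145 at least 4-fold higher. These 4-fold numbers were not recomputed under the other scalings. The higher features made up 11.3% of the counts of the CD14+NP+ library, and the lower features made up 18.8% of the counts of the CD14+NP- library. In 20 sets of Poisson draws with equal levels in both libraries, 0 features reached the 2-fold call, so independent counting error alone gave no such difference at this depth; PCR copies, which are not independent, are not covered. The spread between animals or between repeated sorts is unknown, and with 1 library per population these counts have no replicate check.

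Among CD14- cells the same question gave more features, in nearly equal numbers in each direction. Of 10162 features compared, 1260 were at least 2-fold higher and 1267 at least 2-fold lower in the CD14-NP+ library than in the CD14-NP- library, or 24.9%. At 4-fold the numbers were 393 higher and 383 lower. The higher features made up 22.4% of the counts of the CD14-NP+ library, and the lower features 15.9% of the counts of the CD14-NP- library. Equal-level Poisson draws again gave 0 calls. The balance depended on the processing: plain CPM gave 1090 higher and 1490 lower, and a minimum of 50 CPM in place of 10 gave 786 higher and 481 lower.

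**Figure D1:**
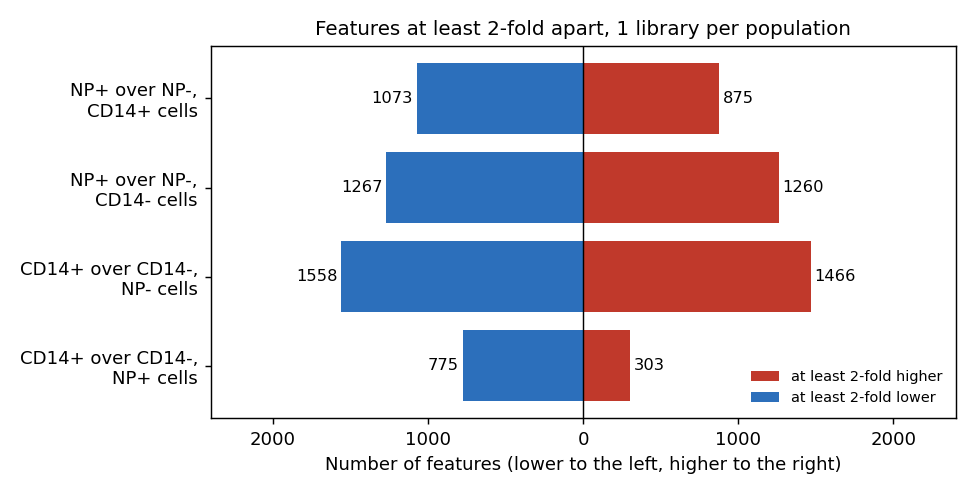
Number of features at least 2-fold higher (red, to the right) and lower (blue, to the left) in each of the 4 comparisons, on the log2(CPM + 1) scale with at least 10 CPM in the higher library and 1 library per population, so there are no error bars. The CD14 comparison in NP+ cells has the fewest, 303 higher and 775 lower, and the CD14 comparison in NP- cells the most, 1466 and 1558.

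The transcripts that differed with nanoparticle signal overlapped between the 2 CD14 sorts, which share no library in this pair of comparisons. For this overlap, calls were made among the 10619 features with at least 10 CPM in any of the 4 libraries, not in the higher of the 2 compared, so the totals exceed those above. Of these, 956 were at least 2-fold higher with NP among CD14+ cells and 1291 among CD14- cells; 501 were higher in both, against 116 for independent lists. Lower in both were 756 features, out of 1328 and 1331, against 166 for independent lists. Some of these 756 were also lower with CD14, both among NP- and among NP+ cells. Of the 501, 300 had both NP+ libraries at least 2-fold above both NP- libraries. Of the 756, 242 had both at least 2-fold below. The others were not separated by NP in that way, so a change in both sorts can go together with a difference by CD14. The 2 sets of log2 ratios had r = 0.64 and rho = 0.57 across features, and 68.9% of features had ratios of the same sign.

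Features at least 4-fold higher in NP+ cells of both sorts, with at least 20 CPM in each NP+ library, numbered 63, and features at least 4-fold lower numbered 123. These features may differ with CD14 as well. ENSMMMG00000001980 led the higher group. Its level was 437 CPM in CD14+NP+ against 18.1 CPM in CD14+NP-, a ratio of 24.2 (95% interval 21.7 to 27.0), and 358 CPM in CD14-NP+ against 11.3 CPM in CD14-NP-, a ratio of 31.6 (27.6 to 36.3). The next, ENSMMMG00000005258, was at 1536 CPM in CD14+NP+ and 78.6 CPM in CD14+NP-, a ratio of 19.6 (18.6 to 20.6). In CD14- cells it was at 1038 CPM with NP and 25.3 CPM without, a ratio of 41.0 (37.5 to 45.0). Between the 2 NP+ libraries both features differed far less, with CD14+ over CD14- ratios of 1.22 (1.18 to 1.26) for ENSMMMG00000001980 and 1.48 (1.45 to 1.51) for ENSMMMG00000005258. These intervals cover counting error only.

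Among the lower features ENSMMMG00000018615 came first on the log2(CPM + 1) scale of the ranking, where its smaller ratio was -4.56 against -4.43 for ENSMMMG00000004271; by the ratios of CPM without the pseudocount the order is the reverse. ENSMMMG00000018615 had 959 counts (49.3 CPM) in CD14+NP- and 22 counts (1.13 CPM) in CD14+NP+, 43.5-fold lower with NP (95% interval 28.6 to 69.8). In CD14- cells it had 7885 counts (414 CPM) without NP and 27 counts (1.53 CPM) with NP, 271-fold lower (186 to 411). ENSMMMG00000004271 came next, with 592 counts in CD14+NP- against 9 in CD14+NP+, 65.7-fold lower (34.4 to 144), and 1356 counts in CD14-NP- against 12 in CD14-NP+, 105-fold lower (59.7 to 203). For both features a difference between the 2 NP+ libraries was not detectable at this depth. The CD14+ over CD14- ratio among NP+ cells was 0.74 (0.40 to 1.35) for ENSMMMG00000018615 and 0.68 (0.25 to 1.76) for ENSMMMG00000004271. Among NP- cells this ratio was 0.119 (0.111 to 0.127) and 0.428 (0.388 to 0.471) in the same order. Both features were thus lower with CD14 there too.

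The third comparison asked how CD14+ and CD14- cells without nanoparticle signal differed. It gave the largest number of features of the 4 comparisons. Of 10115 features compared, 1466 were at least 2-fold higher and 1558 at least 2-fold lower in CD14+NP- than in CD14-NP-, or 29.9%. At 4-fold, 350 were higher and 552 lower. The higher features made up 29.7% of the counts of the CD14+NP- library, and the lower features 15.9% of those of the CD14-NP- library. The balance depended on the processing. Higher features were 48.5% of those called with TMM and 35.8% with plain CPM (1109 higher and 1991 lower), where the log2 ratio of the median feature shifted by -0.21 relative to TMM. With a minimum of 50 CPM, 941 were higher and 517 lower.

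Among NP+ cells the CD14 comparison gave the fewest features and mostly lower ones. Of 9533 features compared, 303 were at least 2-fold higher and 775 at least 2-fold lower in CD14+NP+ than in CD14-NP+, or 11.3%. At 4-fold, 14 were higher and 287 lower. The median size of the log2 ratio was 0.34, against 0.57 for the CD14 comparison in NP- cells. The higher features made up 4.71% of the counts of the CD14+NP+ library and the lower features 7.46% of those of the CD14-NP+ library. The number of features apart by CD14 was 2.81 times larger in NP- than in NP+ cells.

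The CD14 ratios of the NP- and the NP+ cells, again from separate libraries, had r = 0.60 and rho = 0.53 across features. Calls were again made among the 10619 features with at least 10 CPM in any library, which gives larger totals than the comparisons above. Higher in both were 213 features, out of 1506 and 339, against 48.1 for independent lists. Lower in both were 775 features, out of 1612 and 1105, against 168. This overlap shares features with that of the features lower with NP in both sorts, so they are not separate results. Features far higher in CD14-NP- than in CD14+NP+, given below, can enter both. The numbers for independent lists do not address this. Of the 213, 97 had both CD14+ libraries at least 2-fold above both CD14- libraries, and of the 775, 189 had both at least 2-fold below. The standard deviation of the log2 ratios across features was 1.09 in NP- cells and 0.75 in NP+ cells. For 2241 features the CD14 ratio differed at least 2-fold between NP- and NP+ cells, which is the same quantity as the difference of the NP ratio between the 2 CD14 sorts. This interaction was not tested, since no population was repeated.

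**Figure D2:**
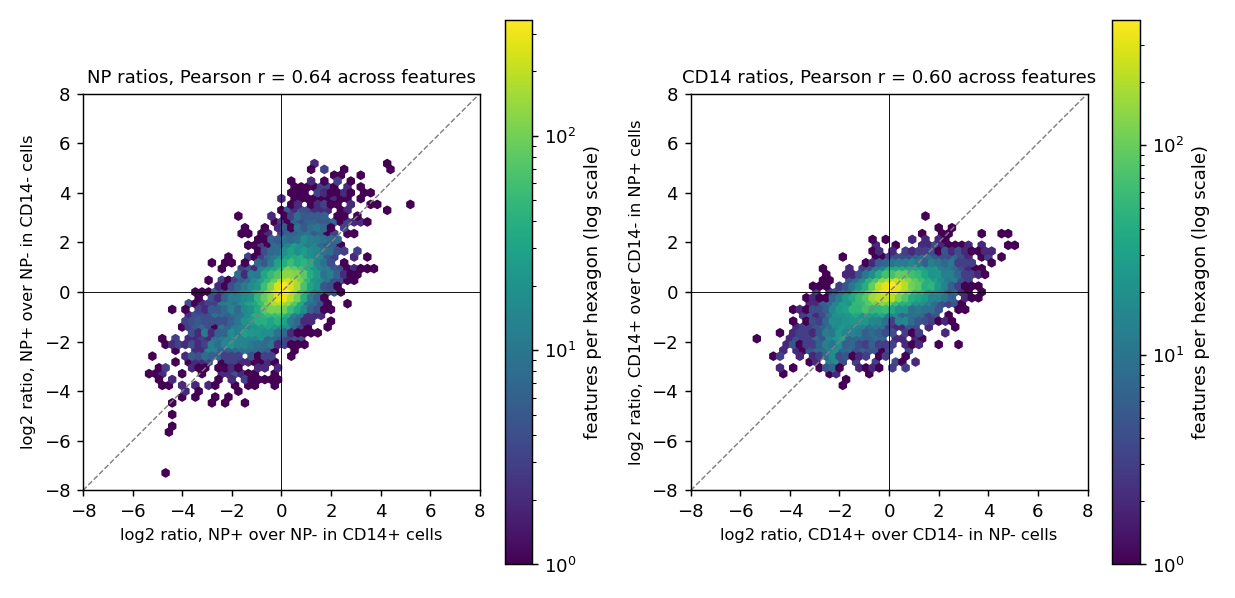
Log2 ratios of the 10619 features in 2 comparisons at a time, as hexagons coloured by the number of features on a log scale, with NP+ over NP- in CD14+ (x axis) and CD14- cells (y axis) on the left and CD14+ over CD14- in NP- (x axis) and NP+ cells (y axis) on the right. The dashed line marks equal ratios; the 2 ratios rise together in both panels (r = 0.64 and r = 0.60), and on the right the CD14 ratios spread less in NP+ cells (SD 0.75) than in NP- cells (SD 1.09).

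The 4 libraries can be split into pairs in 3 ways. Splitting by NP, 300 features had both NP+ libraries at least 2-fold above both NP- libraries and 242 had both at least 2-fold below. Splitting by CD14, 97 features had both CD14+ libraries above and 189 below. The diagonal split, CD14+NP- with CD14-NP+ against the other 2, gave 5 above and 1 below. Without a minimum ratio, the share of features whose pairs did not overlap was 44.2% for NP, 41.3% for CD14 and 14.5% for the diagonal, where chance ordering gives 33.3% for each. A feature without ties falls in exactly 1 of the 3 splits. The 3 shares are therefore not separate results, since a low diagonal share raises the others.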

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

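The other scalings were planned before the data were examined, and the outcome of the depth test was predicted before it was run. Setting the scalings against the pattern below, testing depth and testing shared RNA were chosen after the pattern had been seen. In 31 features nanoparticle signal went with differences of at least 2-fold in opposite directions in the 2 CD14 sorts: 10 were higher with NP among CD14+ cells and lower among CD14- cells, and 21 the reverse. In 44 features the CD14 difference went in opposite directions with and without NP: 43 were higher in CD14+ cells among NP- cells and lower among NP+ cells, and 1 the reverse. Both were flagged because the effect differed in sign between groups, and the difference itself was not tested. Such reversals were rare: 501 features were higher and 756 lower with NP in both CD14 sorts. For CD14, 213 were higher and 775 lower both with and without NP. Independent lists of these sizes would give more reversals than were seen in either case. Few reversals go with the positive correlation of the ratios given above, so this is not a separate result.

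A pattern that stands out is the smaller number of features apart by CD14 in NP+ cells than in NP- cells, 1078 against 3024. The values argue against library scaling as the source, since the ratio of the 2 numbers was at least 2.85 under plain CPM and DESeq2 size factors. They also argue against unequal depth. The 2 NP- libraries together held 38177479 counts and the 2 NP+ libraries 37535921, and when both NP+ libraries were thinned to 10% of their counts the number in NP+ cells went from 1078 to 1355, so that the ratio was still 2.23. A CD14-NP+ library drawing over 50% of its RNA from the same cells as the CD14+NP+ library was also tested. No feature would then be more than 2-fold higher in CD14+NP+, and 114 features had their whole interval, adjusted for the 9533 features compared, above 2, while 6 had it above 4. These intervals cover counting error only and not the spread between library preparations, so shared cells, such as those near the CD14 gate, stay open. So does the biological reading that cells with nanoparticle signal are alike whatever their CD14 signal, which 1 library per population cannot test. The pattern need not lie with the NP+ libraries. The CD14-NP- library was also 3024 features apart from CD14+NP+, and its r with each other library was between 0.71 and 0.81. CD14-NP+ and CD14+NP- were 2558 features apart. Which cells made up each sort was not examined, because the marker lists could not be applied.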

How the results depend on the processing

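The 13 counts and correlations were recomputed under plain CPM, under DESeq2 size factors and after thinning to equal depth, which was added after the data had been seen. The counts all stayed within 1.5 times of the reported value. The correlation between sorts was 0.63 to 0.64 for the NP ratios and 0.60 for the CD14 ratios in these settings. No sampling interval is given for them, since features are not independent. The ratios of the 4 printed features in all 4 comparisons kept their direction under both other scalings. Under plain CPM, 5 of these 16 ratios moved further than their 95% counting intervals reach, and 11 did not. Under DESeq2 size factors none moved that far. The minimum level moved the counts most, by construction, since it changes the number of features compared. With a minimum of 50 CPM, the NP comparison gave 420 higher and 476 lower features in CD14+ cells and 786 and 481 in CD14- cells, and the CD14 comparison gave 941 and 517 in NP- cells and 159 and 254 in NP+ cells. The correlation between sorts became 0.69 for the NP ratios and 0.64 for the CD14 ratios, and the splits of the 4 libraries gave 318 features for NP, 115 for CD14 and 1 for the diagonal. With no minimum, lower features numbered 1972 and 2222 for NP in CD14+ and CD14- cells and 2579 for CD14 in NP- cells, and the CD14 comparison in NP+ cells gave 561 higher and 1626 lower. The correlations were then 0.56 and 0.52, and the diagonal split gave 16. A pseudocount of 5 CPM gave 193 higher features for CD14 in NP+ cells, correlations of 0.61 and 0.58, and splits of 350, 139 and 2 features, and a pseudocount of 0.1 CPM gave a correlation of 0.65 for the NP ratios. The cause of these shifts was not tested further. The alternatives planned for the marker and pathway lists were not run, because the identifiers have no symbols in the files used. Depth limits features with few counts: for both printed lower features, a difference between the 2 NP+ libraries was not detectable at 9 to 27 counts per library.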

Other observations

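All counts and the test in this part were chosen after the data had been seen. The populations differed in how many features set them apart from the other 3. The CD14-NP- library had 204 features at least 4-fold above each other library, making up 6.11% of its counts. The CD14+NP- library had 95 such features (2.37% of its counts) and the CD14-NP+ library 60 (1.70%). The CD14+NP+ library had 2 (0.0337%), and it was the library with the most features at least 4-fold below each other one, 132, against 81 in CD14-NP-, 22 in CD14+NP- and 4 in CD14-NP+.

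A set of 438 features was at least 8-fold higher in CD14-NP- than in CD14+NP+ on the log2(CPM + 1) scale, with at least 20 CPM in CD14-NP-. Of these, 204 (46.6%) lay within 0.5 log2 units of the set's median ratio in both remaining libraries, called the band here, whereas 14.0% of the 143 features at least 8-fold higher in CD14+NP- than in CD14+NP+ did so around their own medians. The second share is no baseline for the first. The 438 were chosen between the least alike libraries, and the 143 between libraries of the same CD14 sort. Those 204 features stood at a median of 21.7% of their CD14-NP- level in CD14+NP-, 24.3% in CD14-NP+ and 5.63% in CD14+NP+. Levels like these are lower with NP and lower with CD14 alike. The 204 features held 5.998% of the counts of CD14-NP-, 1.05% of CD14+NP-, 1.22% of CD14-NP+ and 0.191% of CD14+NP+. One RNA source present in fixed shares, such as 1 cell type carried into the other sorts, may underlie part of the set. Against 1 source for the whole set, 234 of the 438 features lay outside the band. Poisson draws in fixed shares left at most 0.685% outside, but these draws cover counting error only. They do not bear on a source for the 204 features inside. The question stays open, since without repeated libraries the spread that preparation gives to such ratios is unknown. The remaining ratio, CD14+NP+ to CD14-NP-, decides nothing: 51.5% of the features inside the band and 47.9% of those outside lay within 0.5 log2 units of their median, but the set was chosen by this ratio, which cuts off its range in both parts.

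Neighbouring features were compared in the order of the deposited table, among the 10619 features with at least 10 CPM in any library. Features left out in between were skipped, so neighbours need not be adjacent rows. The correlation of their log2 ratios was 0.18 for NP among CD14+ cells, 0.16 for NP among CD14- cells, 0.17 for CD14 among NP- cells and 0.14 for CD14 among NP+ cells. The highest of 1000 shuffles gave 0.034, 0.031, 0.031 and 0.038. No explanation of this was tested.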
